A study of Mus musculus with 16 samples.

How the data were processed

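RNA was sequenced from lower urinary tract mesenchyme of wild-type CD-1 mouse embryos at embryonic day 16.5, in 16 libraries from 4 groups: bladder and pelvic urethra, each from females and males. CD-1 is an outbred stock. Per the labels' protocols, tissue of each sex was pooled within a litter, treated with trypsin on ice and briefly with DNase, and freed of epithelium by forceps. Libraries were made from 250 ng of total RNA by poly(A) selection with a stranded kit and read as 100 bp paired ends on a NovaSeq instrument, also per the labels' protocols. Each replicate number marks a litter, so bladder and urethra libraries of 1 litter and sex come from the same pool of embryos. The libraries are therefore paired between the tissues, and n counts libraries. Within a group each library comes from a different litter. Values over both sexes of a tissue hold each litter once per sex, so n there is not a number of independent litters.

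Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned to GRCm38 with HISAT2 2.1.0 and handled with SAMtools, and counted with Subread 1.6.3. The deposited count table holds read pairs per gene symbol, made per the file headers by featureCounts with strand setting 2, without multimapping reads and without reads that overlap more than 1 gene. Per the file headers the alignment files were named as marked for duplicates. The GENCODE release is not given in the sources used here. Of 53456 symbols that occur once in release 21, 53185 (99.5%) had the same start and end in the count table. The second deposited table holds signal that the authors made by dividing the counts by 1 DESeq2 size factor per library, per the submitters' processing notes. It was used here only to recover these factors, which the values gave to within a relative deviation of 5.3e-15. Size factors computed here from the counts differed from them by at most 8e-16 on the log2 scale.

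Counts of 55228 gene symbols in 16 libraries were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Library totals ran from 18577097 to 29698009 counts, and the 20 largest genes took 6.215, 6, 4.15 and 4.07% of the counts in female bladder, male bladder, female urethra and male urethra. The 37 mitochondrial genes had 0 counts in each library, so mitochondrial content was not used here as a quality measure. Libraries of a group were checked for copies of each other, and over 24 pairs the chi-squared per degree of freedom ran from 4.91 to 37.16.

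The edgeR quasi-likelihood test was used with TMM scaling, filterByExpr, and robust dispersion and quasi-likelihood fits, in 1 fit of the 4 groups. It tested 18254 genes for urethra against bladder (mean of both sexes, and in each sex), for male against female in each tissue, and for the interaction of tissue and sex. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. CPM were computed on TMM-scaled totals, and log2 CPM with a prior count of 2. Log2 fold changes are given with a standard error, and CPM of groups with their SD. That standard error was computed as the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. It is thus an approximation and not an error that the fit itself reports.

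The litter was left out of the fit as a block, and fits with it were alternatives. The pairing, which the labels give, was checked with the correlation of deviations from the group means. For bladder and urethra of the same litter and sex it was 0.13 to 0.51 (median 0.26, 8 of 8 pairs over 0.1), against a median of −0.08 for pairs of other litters. For female and male of the same litter and tissue the median was 0.19, with 5 of 8 pairs over 0.1. With the litter as a replicate block 6887 genes were higher and 7229 lower in the urethra, and with blocks by litter and sex 6920 and 7296.

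There were 26 gene lists, fixed before the data were examined, with 532 genes, of which 531 were in the table and 512 were tested. They covered Hox paralogue groups 1 to 8 and 9 to 13, limb, cloacal and genital transcription factors, smooth and skeletal muscle, epithelium, neuron, glia, endothelium, pericyte, red blood cell, immune cell, mesothelium, genital duct, cartilage and bone, collagen and matrix, the WNT, BMP and TGF-beta, FGF, hedgehog and retinoic acid pathways, steroid hormones, immediate early genes, proliferation, the Y chromosome, and X inactivation and escape. Hoxa11 is in 2 lists. Lists were tested with camera at a correlation of 0.01, adjusted over the 26 lists, and again with the correlation estimated from the data. The number of members called was also counted with p adjusted over the list alone. No folds are given for Y genes or Xist, whose counts in the other sex lie at or near 0.

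Named genes followed a rule that was also set before the data were examined. Between tissues these were the 8 highest and 8 lowest log2 fold changes among called genes with at least 5 CPM in the higher tissue and the same direction in 8 of 8 pairs. From each list up to 2 called members per direction with the largest fold change and at least 1 CPM over all libraries were named. Between sexes the rule took up to 5 autosomal genes per direction with the smallest p, the tested genes of both sex chromosome lists, and up to 2 called members per list and direction. For the interaction it took up to 5 genes per direction. A few genes that the rule names are not reported here. Counts of paralogues that share sequence (Acta1 and Acta2, Hspa1a and Hspa1b, the Hbb genes) are less certain.

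The same steps were tested on simulated data with 200 raised or lowered genes at the real depth and dispersion. For tissue, 78.9, 91.4 and 100% of genes changed by 1.5, 2 and 4-fold were recovered, and 6.8% of calls were unchanged genes. For the sexes in the bladder these were 45.3, 83.6 and 92.5% with 2% false calls, in the urethra 65.6, 83.3 and 100% with 4.1%, and for the interaction 40.3, 67.7 and 84.3% with 0.8%. For tissue in females they were 52.9, 73.4 and 98.4% with 3.3%, and in males 42.3, 87.5 and 92.6% with 5.9%. Of 50 lists of unchanged genes 0 had p under 0.05. Apart from the 200 genes, each gene had the same mean share of the counts in each library. Between the tissues 75% of the tested genes were called in the data. The simulation therefore checks neither the scaling nor the share of false calls where so many genes differ. The simulated genes also varied independently of each other, so this does not check the list test on genes that vary together. In the data the estimated correlation was 0.86 for neuron genes between the sexes in the bladder.

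Alternatives set before the data were examined were DESeq2 size factors, no expression filter, the DESeq2 Wald test, limma-voom, both blocks, fits of only the 8 libraries compared, no genes of X, Y and the mitochondrion, fits without each library in turn, camera with an estimated correlation, and fry. Another 4 were chosen after the data were examined: library totals without TMM factors, counts thinned to the smallest library, the mean log2 CPM of epithelium genes as a covariate, and the 3 libraries lowest in epithelium genes left out together. No library was left out of the main comparisons.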

Results

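Gene expression was measured by poly(A)-selected, strand-specific RNA sequencing in mesenchyme of the lower urinary tract of wild-type CD-1 mouse embryos at embryonic day 16.5. Mesenchyme is the loose embryonic tissue that lies outside the epithelial lining and gives rise to muscle and connective tissue. It was parted from the epithelium with trypsin and forceps, and the tissue of each sex was pooled within a litter. Each of 4 litters gave 4 libraries, 1 each of female bladder, male bladder, female pelvic urethra and male pelvic urethra, for 16 libraries and 4 per group. The study was set up to find genes whose expression marks the bladder or the urethral compartment, and the pools of each sex also allow males and females to be compared within each tissue. The counted fragments came to 18577097 to 22293812 per bladder library and 24447435 to 29698009 per urethra library (n = 8 each). Tissue and depth therefore went together. The first principal component took 78.2% of the variance and parted bladder from urethra, and the second took 6.2% and parted the sexes. The second also went with the mean log2 CPM of epithelium genes among females. In female urethra replicates 1 to 4 that mean was 6.25, 6.17, 5.43 and 4.82, with component values of 11.79, 15.9, 24.52 and 35.37. Sex and epithelium genes are thus not told apart on it.

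**Figure D1:**
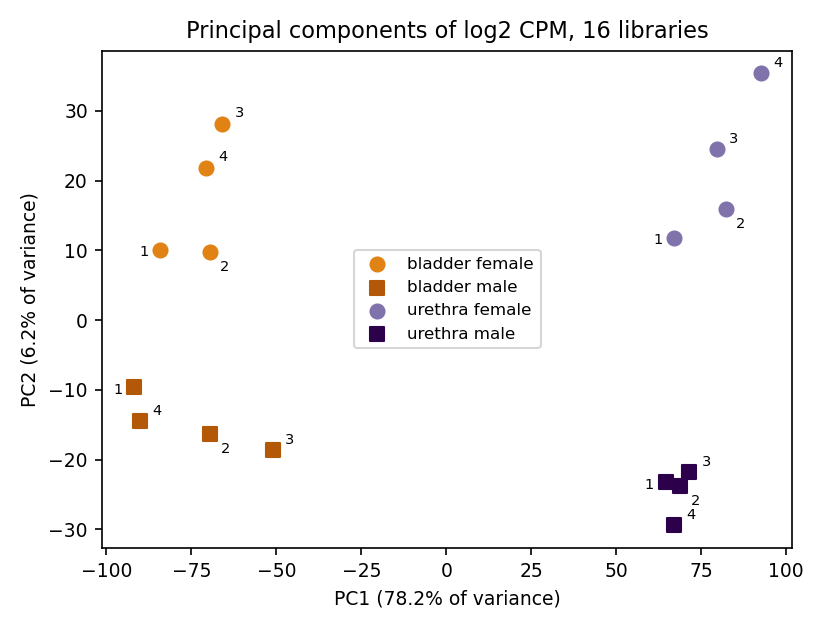
Scores of the 16 libraries on the first 2 principal components of log2 CPM, which took 78.2% (x axis) and 6.2% (y axis) of the variance. Each point is 1 library, coloured by group and numbered by replicate; bladder libraries lie at negative and urethra libraries at positive values of the first component.

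The transcripts of the sex chromosomes went with the sex label in 16 of 16 libraries. Xist, the noncoding RNA that coats the inactive X chromosome, had 6413 to 8970 counts in female and 2 to 7 in male bladder libraries, and 5593 to 9544 against 1 to 9 in the urethra. The Y-linked RNA helicase gene Ddx3y had 2201 to 2473 counts in male and 0 to 3 in female bladder libraries, and 3059 to 3420 against 1 to 3 in the urethra. Kdm5d, a Y-linked histone demethylase gene, had 1283 to 1499 counts in male urethra libraries and 0 in each of the female ones.

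Single genes differed by large folds between the compartments. Genes of skeletal myogenesis lay among the highest in the urethra relative to the bladder: Mybph (myosin binding protein H) by 6.33 ± 0.20 on the log2 scale, Myod1, the master transcription factor of the skeletal muscle lineage, by 5.60 ± 0.22, and Mymk (myomaker), which lets myoblasts fuse, by 5.58 ± 0.30. These are fitted means of both sexes with their standard errors, from 8 libraries per tissue. Srd5a2, the enzyme that turns testosterone into dihydrotestosterone, stood at 17.3 ± 10.2 CPM in the urethra and 0.296 ± 0.211 CPM in the bladder (SD, n = 8), a difference of 5.64 ± 0.24. The homeobox gene Vax1 (5.58 ± 0.34), the zinc finger gene Sall1 (5.31 ± 0.33), the muscle RING finger gene Trim55 (6.47 ± 0.29) and Dlx6os1, a noncoding transcript of the Dlx6 locus (6.55 ± 0.40), completed the 8 highest. In the opposite direction, the genes highest in the bladder were Pvalb (−6.86 ± 0.26), which encodes the calcium buffer parvalbumin, the lipid droplet gene Plin4 (−6.78 ± 0.35), the muscle creatine kinase gene Ckm (−6.40 ± 0.32) and Pln (−6.19 ± 0.31), whose product phospholamban restrains the calcium pump of the sarcoplasmic reticulum. They were followed by the Popeye domain gene Popdc2 (−5.80 ± 0.42), Gm9895 (−5.45 ± 0.13), 9530036M11Rik (−5.42 ± 0.22) and Hhatl (−5.37 ± 0.28). Each of these 16 genes kept its direction in 8 of 8 pairs of bladder and urethra from the same litter and sex.

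On GRCm38, Srd5a2 lies on chromosome 17 from 74016955 to 74047916, Myod1 on chromosome 7 from 46376474 to 46379099, Sall1 on chromosome 8 from 89027235 to 89044162, Pvalb on chromosome 15 from 78191114 to 78206400 and Pln on chromosome 10 from 53337667 to 53345987. Of 18254 genes tested, 6664 were higher and 7019 lower in the urethra at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 2292 and 1718 of them by at least 2-fold. The balance of the directions rests on the scaling. With library totals alone in place of TMM the median of all genes rose by 0.136, and 60.8% rather than 48.7% of the called genes were higher in the urethra, so that tissue differences close to that size have no firm sign.

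**Figure D2:**
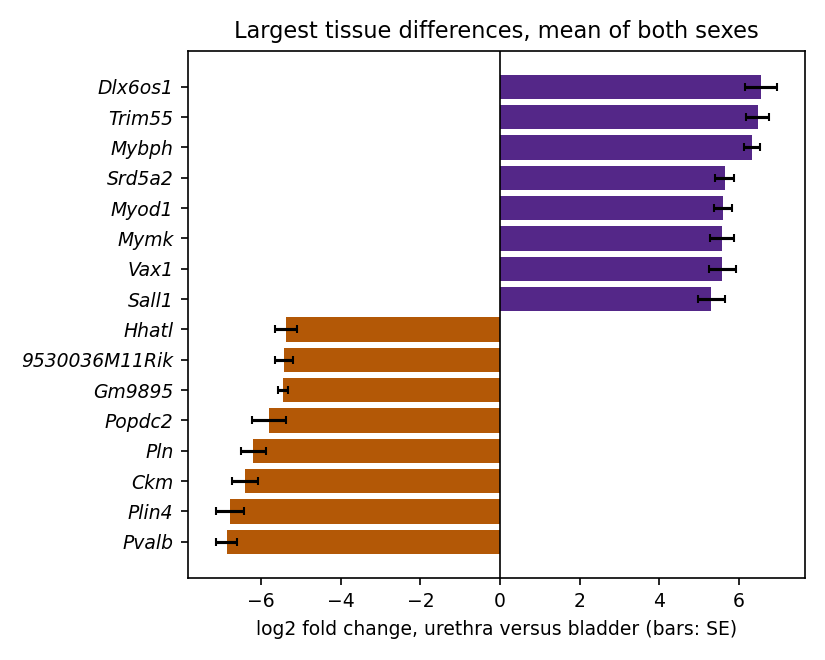
Log2 fold change of urethra against bladder (x axis, mean of both sexes) for the 8 genes with the highest and the 8 with the lowest value under the fixed rule. Bars are fitted values and black lines their standard errors, and the values run from −6.86 for Pvalb to 6.55 for Dlx6os1.

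The contractile genes of smooth muscle were lower in the urethra almost throughout. Of 24 list members 23 fell and 1 rose, with a median of −2.69 (camera, adjusted p = 8.41e-51, and adjusted p = 0.0242 with an estimated correlation). Kcnmb1, a subunit of the calcium-activated potassium channel of smooth muscle, stood at 63.7 ± 10.5 CPM in the bladder and 3.29 ± 0.965 CPM in the urethra (SD, n = 8), and the intermediate filament gene Synm fell by 3.68 ± 0.20. The exception was Itga8, an integrin subunit (0.38 ± 0.09). Skeletal muscle genes went the other way, with 20 of 26 higher in the urethra and 6 lower and a median of 3.82 (adjusted p = 8.67e-07, and adjusted p = 0.243 with an estimated correlation). Chrng, the fetal subunit of the muscle acetylcholine receptor, rose by 6.30 ± 0.36. The 6 lower members were led by Ckm (220 ± 29 CPM in the bladder, 2.64 ± 2.18 in the urethra) and the skeletal actin gene Acta1 (1210 ± 187 and 34 ± 17 CPM, SD, n = 8). Acta1 is nearly identical in its coding sequence to the other actin genes, so its count is uncertain where reads fall in shared sequence. Of 11 mesothelium genes, which mark the outer lining of the bladder, 9 fell and 1 rose (median −2.72, adjusted p = 3.74e-04, and adjusted p = 0.352 with an estimated correlation). The tight junction gene Cldn15 fell by 4.01 ± 0.22 and the mucin gene Muc16 by 3.81 ± 0.30, while the retinaldehyde dehydrogenase gene Aldh1a1 rose (0.64 ± 0.11), with that direction in only 4 of 8 pairs.

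Positional and patterning genes were mostly higher in the urethra. Among the posterior Hox genes of paralogue groups 9 to 13, which pattern the caudal body, 11 of 14 rose and 0 fell (median 1.03, adjusted p = 9.79e-05, and adjusted p = 0.108 with an estimated correlation). Hoxc10 (2.06 ± 0.14) and Hoxc9 (2.00 ± 0.17) led. In groups 1 to 8, 13 of 22 rose and 3 fell (median 0.42, adjusted p = 0.0331, and adjusted p = 0.466 with an estimated correlation). Hoxb3 stood at 39.5 ± 2.67 CPM in the urethra and 8.61 ± 1.58 CPM in the bladder (SD, n = 8), Hoxb8 rose by 1.59 ± 0.08 and Hoxd8 fell (−0.69 ± 0.06). That list was no longer called with library totals alone (adjusted p = 0.0713) or without bladder male replicate 3 (adjusted p = 0.0651). Of 41 transcription factors of limb, cloacal and genital development, 29 rose and 7 fell (median 1.30, adjusted p = 1.73e-04, and adjusted p = 0.214 with an estimated correlation). Sall1 and the homeobox gene Dlx6 (4.82 ± 0.39) led those that rose. Among those that fell was Pitx1, a homeobox gene of hindlimb patterning (−2.93 ± 0.08).

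Signalling genes of several pathways also differed between the tissues. Of 17 retinoic acid pathway genes 16 rose and 0 fell (median 0.93, adjusted p = 4.67e-07, and adjusted p = 0.0279 with an estimated correlation). Stra6, the receptor for retinol binding protein (3.74 ± 0.24), rose, as did Cyp26a1, which degrades retinoic acid (3.22 ± 2.08 CPM in the urethra, 0.198 ± 0.0596 CPM in the bladder, SD, n = 8). Of 18 steroid hormone genes 12 rose and 5 fell (median 1.43, adjusted p = 0.00127, and adjusted p = 0.205 with an estimated correlation). The oestrogen-responsive gene Greb1 rose by 2.51 ± 0.19, and Srd5a1, the other steroid 5-alpha-reductase, fell (−1.28 ± 0.14). In the WNT pathway 27 of 41 rose and 11 fell (median 0.82, adjusted p = 2.03e-04, and adjusted p = 0.203 with an estimated correlation). The secreted WNT antagonists Wif1 (4.19 ± 0.15) and Dkk1 (3.93 ± 0.30) were among the former, the ligand gene Wnt2b (−2.13 ± 0.14) and the R-spondin receptor gene Lgr6 (−2.10 ± 0.13) among the latter. In the BMP and TGF-beta pathway 24 of 39 rose and 8 fell (median 0.58, adjusted p = 0.00203, and adjusted p = 0.214 with an estimated correlation). The ligand gene Gdf7 (4.79 ± 0.33) and the BMP antagonist gene Grem1 (3.92 ± 0.21) were higher, and Chrdl2 (−2.54 ± 0.20) and the inhibin subunit gene Inhbb (−1.44 ± 0.17) lower. In the FGF pathway 13 of 25 rose and 3 fell (median 0.36, adjusted p = 0.0162, and adjusted p = 0.214 with an estimated correlation). The FGF target Etv4 was higher (3.03 ± 0.15) and the ligand gene Fgf5 lower (−3.05 ± 0.28). Of 15 hedgehog pathway genes 9 rose and 3 fell, and the list was not called (median 0.29, adjusted p = 0.258). Foxf2 rose by 1.92 ± 0.11 and its relative Foxf1 was lower (−0.44 ± 0.09). Without the expression filter that list was called (adjusted p = 0.0464), as it was by fry (adjusted p = 4.32e-04).

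Genes of other cell types that such a dissection can hold also differed between the tissues. All 20 neuron genes rose (median 3.88, adjusted p = 4.97e-07, and adjusted p = 0.34 with an estimated correlation). They included Slc18a3, the vesicular acetylcholine transporter (4.69 ± 0.45), and the nicotinic receptor subunit gene Chrna3 (4.41 ± 0.44). Of 14 glia genes 12 rose and 1 fell (median 2.11, adjusted p = 1.19e-04, and adjusted p = 0.214 with an estimated correlation). Gfra3, the artemin co-receptor, stood at 3.36 ± 0.23 and Mal at −1.77 ± 0.21. Of 16 endothelium genes 13 rose and 2 fell (median 0.68, adjusted p = 0.0499, and adjusted p = 0.555 with an estimated correlation). The lymphatic transcription factor gene Prox1 rose by 2.75 ± 0.25, while the lymphatic receptor gene Lyve1 fell (−1.46 ± 0.12). Of 9 genital duct genes, markers of the Wolffian and Müllerian ducts, 6 rose and 1 fell (median 2.66, adjusted p = 0.0499, and adjusted p = 0.492 with an estimated correlation). Wnt7a (4.34 ± 0.53) and Lhx1 (3.47 ± 0.41) led. Of 14 cartilage and bone genes 7 rose and 2 fell (median 0.47, adjusted p = 0.0499, and adjusted p = 0.329 with an estimated correlation). The cartilage collagen gene Col2a1 rose by 3.60 ± 0.18 and Ibsp, bone sialoprotein, fell (−3.59 ± 0.25). The last 3 calls lay at the threshold. Endothelium lost it in 13 of 26 alternatives (adjusted p = 0.0504 to 0.555), genital duct in 16 (0.0515 to 0.492) and cartilage and bone in 18 (0.052 to 0.329), and with the litter as a block the genital duct and cartilage lists had adjusted p = 0.107 and 0.0739.

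Proliferation genes were lower in the urethra, 17 of 20 with 0 higher (median −0.57, adjusted p = 7.70e-06, and adjusted p = 0.214 with an estimated correlation), as with the survivin gene Birc5 (−0.89 ± 0.06) and the cyclin gene Ccna2 (−0.87 ± 0.04). Epithelium genes, a measure of lining left on the mesenchyme, were not called as a list (median −0.42, adjusted p = 0.275). They were called without the expression filter (0.0446) and by fry (0.0489). In that list 12 of 24 fell, led by the uroplakin genes Upk3a (−2.84 ± 0.29) and Upk2 (−2.41 ± 0.25). In the other direction 3 rose, led by Prom1 (1.81 ± 0.09) and the basal keratin gene Krt14 (1.78 ± 0.29). The mean log2 CPM of that list was 6.64 ± 0.43 in bladder and 6.04 ± 0.61 in urethra libraries (SD, n = 8).

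The remaining lists were not called by camera either. Among them 15 of 34 collagen and matrix genes fell and 10 rose (median −0.14, adjusted p = 0.508), with Tnxb at −2.47 ± 0.20 and the collagen gene Col8a1 at 2.56 ± 0.21. Of 8 pericyte genes 5 fell and 3 rose (median −0.46, adjusted p = 0.746), as with Ndufa4l2 (−2.29 ± 0.12) and the potassium channel gene Kcnj8 (1.56 ± 0.08). Of 15 immune cell genes 6 rose and 4 fell (median 0.14, adjusted p = 0.773), with the leukocyte antigen gene Ptprc at 0.57 ± 0.10 and the lysozyme gene Lyz2 at −0.75 ± 0.11. Of 12 red blood cell genes 6 fell (median −0.46, adjusted p = 0.359), among them the haemoglobin gene Hbb-bs (−0.78 ± 0.09), which shares reads with its near-identical neighbour. Hbb-y (−0.73 ± 0.29), another of the 6, lost its call in 15 of 26 alternatives. Of 19 immediate early genes 9 fell and 7 rose (median −0.20, adjusted p = 0.197), with the transcription factor gene Egr3 at 1.93 ± 0.16 and the heat shock gene Hspa1b, which shares reads with Hspa1a, at −2.18 ± 0.10. Of 11 genes of X inactivation and escape 6 rose and 2 fell (median 0.12, adjusted p = 0.486), with Kdm6a at 0.54 ± 0.04, and 0 of 4 tested Y genes changed (adjusted p = 0.916). Adjusted over the list alone, each of the tissue counts above was the same except those of red blood cell genes, of which 4 fell, and genital duct genes, of which 7 rose.

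**Figure D3:**
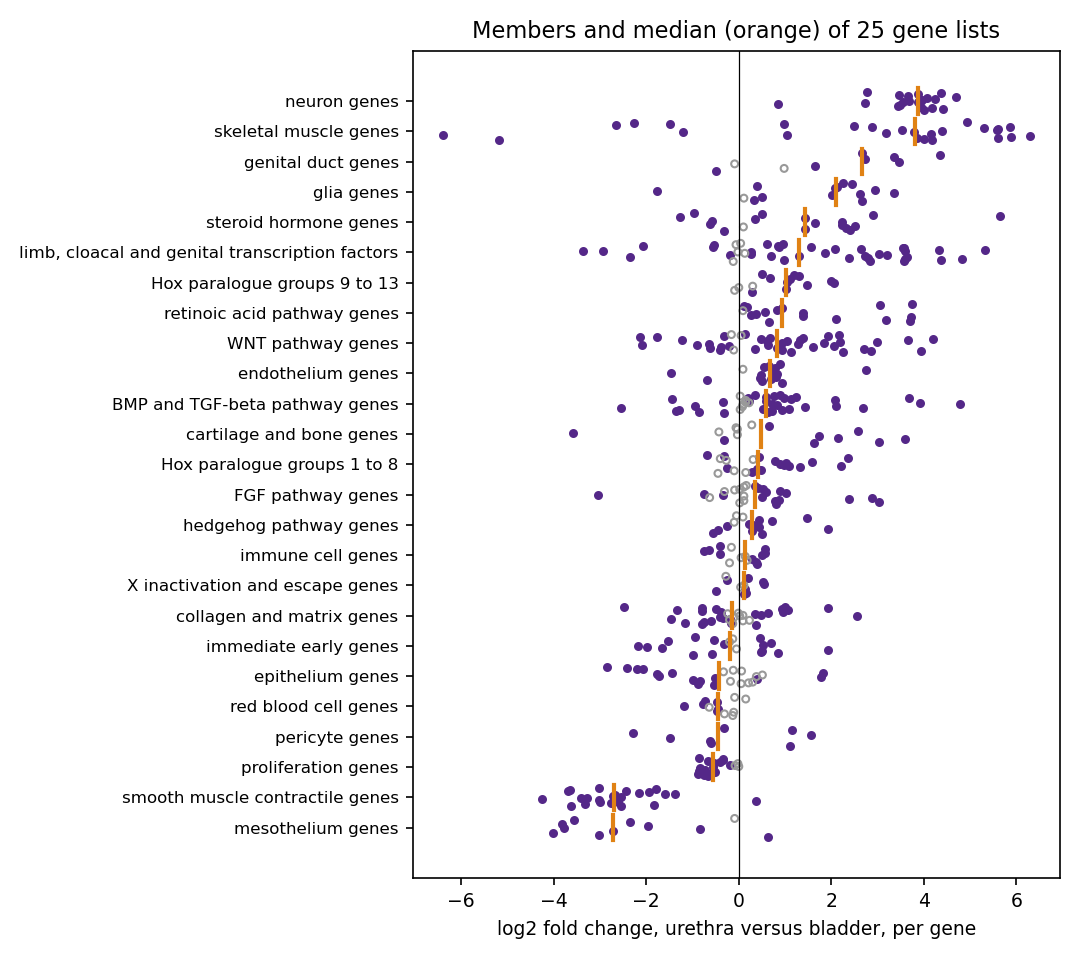
Log2 fold change of urethra against bladder (x axis, mean of both sexes) for each tested member of each fixed gene list except the Y chromosome list. Filled points had an adjusted p under 0.05, open points did not, and orange bars mark list medians, which run from −2.72 for mesothelium genes to 3.88 for neuron genes.

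The tissue difference was also tested within each sex. In females 5950 genes were higher and 6051 lower in the urethra, and in males 5727 and 5952, from 4 libraries per group. Called in both sexes were 5104 higher genes, where 1866.7 would be shared by independent lists of these sizes, and 5242 lower genes, where 1973 would be, and 36 genes were called in opposite directions. The comparisons in females and in males use different libraries. Library totals alone moved the share of higher genes from 49.6% to 61.1% in females, where the median of all genes rose by 0.128, and from 49.0% to 63.3% in males, where it rose by 0.143.

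In the urethra, single genes differed strongly between males and females. Nt5e, the enzyme CD73 that makes adenosine from AMP, stood at 57.9 ± 2.05 CPM in males and 7.94 ± 0.54 CPM in females (SD, n = 4 each), a log2 difference of 2.87 ± 0.14. The hyaluronan binding protease gene Habp2 (4.88 ± 0.31), the glucagon-like peptide receptor gene Glp2r (3.76 ± 0.24), Ramp1, which pairs with the CGRP receptor (1.70 ± 0.11), and the transcription factor gene Stat5a (1.46 ± 0.10) were also higher in males. The estrogen receptor gene Esr1 was lower in males, at 16.3 ± 1.41 against 58.1 ± 7.16 CPM (SD, n = 4 each), as was Foxl2, a forkhead gene of ovary development, at 0.35 ± 0.0835 against 2.81 ± 0.0911 CPM. The other genes lower in males with the smallest p were Pamr1 (−0.97 ± 0.07), the desmosomal cadherin gene Dsc3 (−2.34 ± 0.21), the carboxypeptidase family gene Cpxm2 (−2.53 ± 0.25) and Lrrtm1 (−1.28 ± 0.13). Each of these 11 genes went the same way in 4 of 4 litters. Nt5e lies on chromosome 9 from 88327197 to 88372092 and Esr1 on chromosome 10 from 4611593 to 5005614.

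Of the 18254 genes, 725 were higher and 442 lower in male urethra, 697 and 413 of them off the sex chromosomes. The epithelium score, the mean log2 CPM of epithelium genes, was 6.42 ± 0.19 in male and 5.67 ± 0.67 in female urethra libraries (SD, n = 4), with female replicates 3 and 4 lowest at 5.43 and 4.82. Without those 2 libraries and the lowest bladder female library, 314 genes were higher and 128 lower in males, and with the score as a covariate 353 and 138. Only 35.4% and 37.2% of the 1167 calls were kept in these fits, which were added after the data were examined. The first of them also has fewer female urethra libraries, so its fall in calls does not by itself measure the part of epithelium. When only urethra male replicate 4 was left out, whose score was 6.62, 57% of the calls were kept. Leaving out urethra male replicate 4 gave 447 and 227, the lowest counts of the single-library series, and leaving out urethra female replicate 1 gave 897 and 794, the highest.

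The gene lists in the urethra held sex differences of hormone and patterning genes. Of 18 steroid hormone genes 7 rose in males and 3 fell (median 0.05, adjusted p = 0.00727, and adjusted p = 0.386 with an estimated correlation), and 7 and 4 did so adjusted over the list alone. The zinc finger gene Zbtb16 rose by 2.30 ± 0.31. That list was not called without the expression filter (adjusted p = 0.0637). Hox genes of groups 1 to 8 were higher in males (5 of 22 rose and 0 fell, or 7 and 0 adjusted over the list alone, median 0.25, adjusted p = 0.00269, and adjusted p = 0.543 with an estimated correlation), led by Hoxd4 (0.97 ± 0.18), and Hoxb5 (0.59 ± 0.15) lost its call in 5 of 26 alternatives. As a list they were not called with the epithelium covariate (adjusted p = 0.0581). Of 14 cartilage and bone genes 3 rose and 0 fell under either adjustment (median 0.19, adjusted p = 0.0128, and adjusted p = 0.386 with an estimated correlation), with Ibsp at 3.24 ± 0.43 and the chondromodulin gene Cnmd at 2.99 ± 0.31. Of 11 mesothelium genes 3 rose and 0 fell, also adjusted over the list alone (median 0.41, adjusted p = 4.51e-04, and adjusted p = 0.583 with an estimated correlation). The leading member was Aldh1a1, at 74.6 ± 9.75 CPM in males and 13.3 ± 3.52 CPM in females (SD, n = 4 each), and Msln (1.29 ± 0.31) lost its call in 5 of 26 alternatives.

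Epithelium genes were higher in male urethra as a list, with 4 of 24 called and 0 lower, or 6 and 0 adjusted over the list alone (median 0.63, adjusted p = 2.82e-07, and adjusted p = 0.602 with an estimated correlation). Krt7, a simple-epithelium keratin, was 1.08 ± 0.27 higher and the ligand gene Shh 1.02 ± 0.25. The calls of both genes were lost with only the urethra libraries in the fit (adjusted p = 0.0534 and 0.055), without the 3 libraries lowest in epithelium genes (adjusted p = 0.0502 and 0.09), without urethra female replicate 3 (0.0835 and 0.0827), without urethra male replicate 1 (0.0605 and 0.0503) and without urethra male replicate 4 (0.0754 and 0.0787). Proliferation genes were lower in males (3 of 20 fell and 0 rose, or 8 and 0 adjusted over the list alone, median −0.14, adjusted p = 3.38e-04, and adjusted p = 0.543 with an estimated correlation). Of the 3 members Cenpf (−0.38 ± 0.11) lost its call in 21 of 26 alternatives and Bub1b (−0.25 ± 0.05) in 3. Red blood cell genes were lower as a list, with none of 12 called under either adjustment, that is 0 adjusted over the list alone (median −0.38, adjusted p = 0.0281, and adjusted p = 0.602 with an estimated correlation). The latter call was lost without urethra female replicate 3 (adjusted p = 0.0713), urethra male replicate 3 (0.0593) or urethra male replicate 4 (0.0698). Limb, cloacal and genital transcription factors were lower as a list (2 rose and 1 fell of 41, or 2 and 5 adjusted over the list alone, median −0.19, adjusted p = 0.0241, and adjusted p = 0.602 with an estimated correlation), although the orphan nuclear receptor gene Nr2f2 rose (0.31 ± 0.07). The 1 that fell, Alx4 (−0.82 ± 0.20), lost its call in 6 of 26 alternatives. The list call was lost without urethra female replicate 4 (adjusted p = 0.0532) or urethra male replicate 2 (0.0576), without the 3 libraries lowest in epithelium genes (0.0738) and with the epithelium covariate (0.186).

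Other lists in the urethra were not called between the sexes. Their members included 5 of 41 WNT pathway genes that rose and 4 that fell, or 7 and 9 adjusted over the list alone (median −0.07, adjusted p = 0.974), with Wnt16 at 1.81 ± 0.26 and Wif1 at 1.64 ± 0.15. Rspo2 (−1.07 ± 0.30), 1 of the 4, lost its call in 16 of 26 alternatives. Of 39 BMP and TGF-beta genes 3 rose and 7 fell, or 4 and 8 adjusted over the list alone (median −0.16, adjusted p = 0.144), with the joint-forming ligand gene Gdf5 at −1.60 ± 0.17, Grem1 at −1.52 ± 0.21 and Bmper at 0.77 ± 0.12. Of 17 retinoic acid genes 3 rose and 2 fell, or 4 and 2 adjusted over the list alone (median −0.03, adjusted p = 0.372), with Cyp26a1 at 1.93 ± 0.13, the retinaldehyde dehydrogenase gene Aldh1a3 at 1.53 ± 0.23 and the receptor gene Rarb at −0.37 ± 0.06. Of 25 FGF genes 3 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.03, adjusted p = 0.381), with the mesenchymal ligand gene Fgf10 at 0.75 ± 0.16, and Fgfr3 (0.93 ± 0.24) lost its call in 7 of 26 alternatives. Of 9 genital duct genes 1 rose, Wnt9b, from 0.992 ± 0.282 CPM in females to 13.3 ± 2.24 CPM in males (SD, n = 4 each), and 1 fell, the anti-Müllerian hormone receptor gene Amhr2 (−2.38 ± 0.56), or 2 and 2 adjusted over the list alone (median 0.04, adjusted p = 0.162). The genital duct list was called without urethra male replicate 4 (adjusted p = 0.0371) and with the epithelium covariate (0.0131). The Amhr2 call was lost in 5 of 26 alternatives, among them without urethra male replicate 1 (adjusted p = 0.0595), 2 (0.0505) or 4 (0.0688). Of 34 collagen and matrix genes 1 rose and 2 fell, or 2 and 3 adjusted over the list alone (median −0.03, adjusted p = 0.667). The 1 that rose, Col18a1 (0.22 ± 0.06), lost its call in 13 of 26 alternatives. Among those that fell was the fibulin gene Fbln1 (−0.37 ± 0.07), which was not called with the epithelium covariate (adjusted p = 0.0585). With that covariate the collagen and matrix list turned to the higher side (adjusted p = 0.0495) and the FGF list was called (0.0495). Of the posterior Hox genes 1 of 14 rose and 0 fell, Hoxb9 (0.61 ± 0.09), or 3 and 3 adjusted over the list alone (median −0.10, mean 0.00, adjusted p = 0.865). Of 19 immediate early genes 1 rose and 0 fell, also adjusted over the list alone (median 0.11, adjusted p = 0.44).

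Among the genes of the X inactivation list in the urethra 7 of 11 were lower in males and 1, the midline gene Mid1, higher (0.37 ± 0.09), or 8 and 2 adjusted over the list alone (adjusted p = 4.96e-07 with an estimated correlation). The Mid1 call was lost without urethra male replicate 3 (adjusted p = 0.0547). The translation factor gene Eif2s3x, which escapes X inactivation, was lower (−0.70 ± 0.05). All 4 tested Y genes rose, also adjusted over the list alone (adjusted p = 1.33e-11 with an estimated correlation). No member was called over all genes for smooth muscle (median −0.05, adjusted p = 0.432), skeletal muscle (median −0.09, adjusted p = 0.53), neuron (median −0.30, adjusted p = 0.372), glia (median −0.22, adjusted p = 0.44), endothelium (median 0.04, adjusted p = 0.372), pericyte (median 0.03, adjusted p = 0.816), immune cell (median −0.13, adjusted p = 0.151) or hedgehog genes (median −0.07, adjusted p = 0.44). Adjusted over the list alone, 2 endothelium genes rose and 0 members of the other 7 lists changed. Immune cell genes were called without urethra female replicate 4 or urethra male replicate 2 (adjusted p = 0.0398 each) and without the expression filter (0.0191), skeletal muscle genes without urethra male replicate 2 (0.0237), and endothelium genes with the epithelium covariate (0.00617).

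In the bladder the sexes differed in fewer genes. Pnoc, the precursor of the neuropeptide nociceptin, was higher in males by 5.03 ± 0.49, at 5.02 ± 2.15 against 0.15 ± 0.142 CPM (SD, n = 4 each). Lower in males were the retinoic acid binding protein gene Crabp1, at 5.74 ± 2.15 against 20.8 ± 5.44 CPM, the matrix glycoprotein gene Emilin2, at 8.06 ± 1.4 against 17 ± 2.6 CPM, and Tbx18, a T-box gene of ureter mesenchyme, at 14.3 ± 1.28 against 24.6 ± 3.92 CPM (SD, n = 4 each). The metalloprotease gene Adam12 (−0.74 ± 0.10) and the forkhead gene Foxd1 (−1.96 ± 0.27) were lower too. Ndrg2 (0.54 ± 0.07), the diacylglycerol lipase gene Daglb (0.51 ± 0.08) and the double-stranded RNA receptor gene Tlr3 (0.72 ± 0.12) were higher in males. Each of these 9 genes went the same way in 4 of 4 litters. With only the 8 bladder libraries in the fit, Crabp1 (adjusted p = 0.0571), Tbx18 (0.0508), Ndrg2 (0.0502), Daglb (0.0798) and Tlr3 (0.0796) were no longer called, and the Tlr3 call was also lost without bladder female replicate 4 (0.0705). In all, Tlr3 lost its call in 4 and Daglb in 2 of 26 alternatives.

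In all 45 genes were higher and 61 lower in male bladder, 40 and 48 of them off the sex chromosomes, and library totals alone moved the share of higher calls from 42.5% to 53.3%. The epithelium score was 6.94 ± 0.15 in male and 6.34 ± 0.41 in female bladder libraries (SD, n = 4). With the score as a covariate 10 genes were higher and 20 lower, and without the 3 libraries lowest in epithelium genes 18 were higher and 54 lower, and 27.4% and 50% of the 106 calls were kept in these fits. Single libraries moved the counts from 10 higher and 30 lower without bladder female replicate 4 to 82 higher without bladder female replicate 1 and 103 lower without bladder female replicate 2. With only the 8 bladder libraries in the fit 8 genes were higher and 8 lower, and 15 of the 106 calls (14.2%) were kept, and the DESeq2 test gave 231 and 249. The bladder counts are thus a rough size only.

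Of the lists in the bladder, camera at the fixed correlation called those of connective tissue and blood-borne cells lower in males. With an estimated correlation these lists were not called. Chance is not excluded for the number of bladder lists called, since 13 of 35 groupings of the libraries, the real one among them, gave at least 12. Collagen and matrix genes had 2 of 34 lower and 0 higher, or 11 and 1 adjusted over the list alone (median −0.25, adjusted p = 3.37e-11, and adjusted p = 0.263 with an estimated correlation). The members with the largest change were Tnc (−0.82 ± 0.16) and Postn (−0.63 ± 0.12), both matrix glycoproteins. Their calls were lost without bladder female replicate 3 (adjusted p = 0.0911 and 0.0796), bladder female replicate 4 (0.16 and 0.141) or bladder male replicate 4 (0.0779 and 0.0817). The Postn call was also lost without bladder male replicate 1 (0.0813) or 2 (0.071). With only the bladder libraries in the fit Tnc, Postn and Gdf10 had adjusted p = 0.122, 0.115 and 0.0853. In all, Tnc lost its call in 7 and Postn in 9 of 26 alternatives. Immune cell genes had 1 of 15 lower and 0 higher, or 7 and 0 adjusted over the list alone (median −0.27, adjusted p = 2.45e-07, and adjusted p = 0.128 with an estimated correlation). The 1 called member, Adgre1 (−0.49 ± 0.11), lost its call in 21 of 26 alternatives. Red blood cell genes had none of 12 called, or 4 lower and 0 higher adjusted over the list alone (median −0.43, adjusted p = 6.26e-05, and adjusted p = 0.263 with an estimated correlation). Endothelium genes had none of 16 called, or 1 lower and 0 higher adjusted over the list alone (median −0.29, adjusted p = 1.23e-04, and adjusted p = 0.351 with an estimated correlation), and were not called with the epithelium covariate (adjusted p = 0.0636). Limb, cloacal and genital transcription factors had 1 of 41 lower, Tbx18, or 6 adjusted over the list alone, and 0 higher (median −0.11, adjusted p = 2.43e-04, and adjusted p = 0.274 with an estimated correlation). BMP and TGF-beta genes had 1 of 39 lower, Gdf10 (−1.27 ± 0.20), or 6 lower and 1 higher adjusted over the list alone (median −0.13, adjusted p = 0.00176, and adjusted p = 0.263 with an estimated correlation), and were not called with the epithelium covariate (adjusted p = 0.199). Retinoic acid genes had 1 of 17 lower, Crabp1, or 5 lower and 0 higher adjusted over the list alone (median −0.03, adjusted p = 0.0175, and adjusted p = 0.274 with an estimated correlation), and were not called without bladder female replicate 2 (adjusted p = 0.0632) or bladder male replicate 4 (0.0641), or with the epithelium covariate (0.0529). Pericyte genes had 0 of 8 called, or 2 lower and 0 higher adjusted over the list alone (median −0.11, adjusted p = 0.0481, and adjusted p = 0.429 with an estimated correlation), and lost the call in 17 of 25 alternatives (adjusted p = 0.0514 to 0.429).

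Epithelium genes were higher in male bladder as a list (median 0.59, adjusted p = 1.29e-08, and adjusted p = 0.404 with an estimated correlation) with none of 24 called, and 0 adjusted over the list alone. Neuron genes were higher as a list (median 0.92, adjusted p = 0.00828, and adjusted p = 0.825 with an estimated correlation) with none of 20 called, and 0 adjusted over the list alone. The mean log2 CPM of neuron genes was 3.07 ± 1.33 in male and 2.67 ± 0.33 in female bladder (SD, n = 4). Without bladder male replicate 3 the neuron list turned to the lower side (adjusted p = 0.513), and without bladder female replicate 1 it was not called (0.0584), nor with the epithelium covariate (0.0529). In the X inactivation list 7 of 11 were lower and 0 higher in male bladder, or 8 and 2 adjusted over the list alone (adjusted p = 3.79e-08 with an estimated correlation), as with Eif2s3x (−0.63 ± 0.05) and the histone demethylase gene Kdm6a (−0.53 ± 0.06). Of these members Ddx3x (−0.32 ± 0.06) lost its call in 8 of 26 alternatives. All 4 tested Y genes rose, also adjusted over the list alone (adjusted p = 1.03e-13 with an estimated correlation).

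The other bladder lists were not called between the sexes. Of 41 WNT genes 2 were lower, Sfrp4 (−1.96 ± 0.34) and Dkk2 (−1.24 ± 0.23), both secreted WNT modulators, and 0 higher, or 6 and 1 adjusted over the list alone (median 0.00, mean −0.05, adjusted p = 0.232). The Dkk2 call was lost in 7 of 26 alternatives, among them without bladder female replicate 3 (adjusted p = 0.0573), bladder female replicate 4 (0.118) or bladder male replicate 2 (0.059). With only the bladder libraries Sfrp4 and Dkk2 had adjusted p = 0.106 and 0.111. The WNT list was called without bladder male replicate 3 (adjusted p = 0.0461). Of 18 steroid hormone genes 1 was higher, and 1 higher and 1 lower adjusted over the list alone (median 0.04, adjusted p = 0.79). That gene was the estrogen sulfotransferase gene Sult1e1 (3.09 ± 0.67), chosen after its values were seen. No member was called over all genes for Hox groups 1 to 8 (median −0.08, adjusted p = 0.252), Hox groups 9 to 13 (median −0.07, adjusted p = 0.516), smooth muscle (median −0.03, adjusted p = 0.475), skeletal muscle (median 0.05, mean −0.09, adjusted p = 0.769), glia (median 0.13, adjusted p = 0.769), mesothelium (median 0.13, adjusted p = 0.769), genital duct (median −0.62, adjusted p = 0.728), cartilage and bone (median 0.01, mean −0.03, adjusted p = 0.769), FGF (median −0.03, mean 0.01, adjusted p = 0.457), hedgehog (median −0.05, adjusted p = 0.475), immediate early (median 0.06, adjusted p = 0.79) or proliferation genes (median −0.05, adjusted p = 0.204). Adjusted over the list alone, 1 glia and 1 genital duct gene were higher, 1 smooth muscle, 1 skeletal muscle, 1 glia and 1 genital duct gene lower, and 0 members of the other lists changed. Single libraries brought calls of Hox groups 1 to 8 (adjusted p = 0.0091 without bladder female replicate 3), smooth muscle (0.031 without bladder female replicate 2), mesothelium (0.0322 without bladder male replicate 3) and proliferation genes (0.0234 without bladder female replicate 4 and 0.0039 without bladder male replicate 1). Hox groups 1 to 8 were also called with the epithelium covariate (0.0463) and without the 3 libraries lowest in epithelium genes (0.0145).

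**Figure D4:**
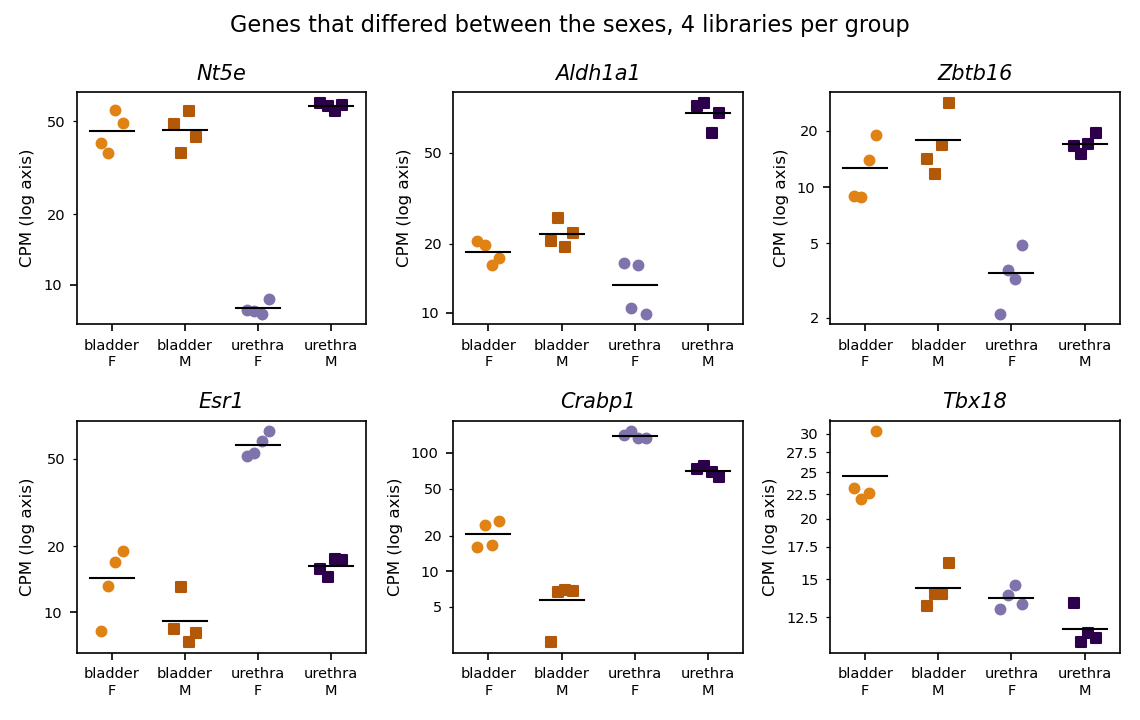
CPM (y axis, log scale, ranges differ between panels) of 6 genes in each of the 16 libraries by tissue and sex (F female, M male). Points are libraries and lines group means: Nt5e, Aldh1a1 and Zbtb16 were higher and Esr1 lower in male than in female urethra, and Crabp1 and Tbx18 were lower in male than in female bladder.

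**Figure D5:**
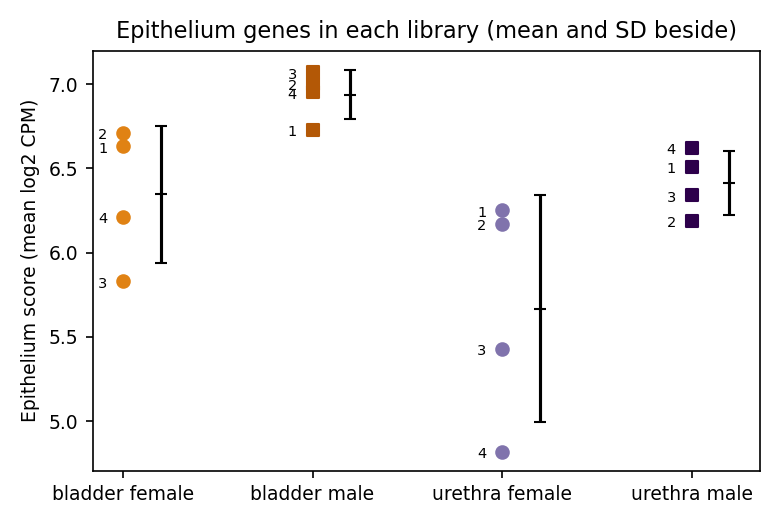
Mean log2 CPM of the epithelium genes (y axis) in each library, numbered by replicate, with the group mean and SD beside the points. Female urethra replicates 3 and 4 (5.43 and 4.82) and female bladder replicate 3 (5.83) lie lowest in their groups.

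Whether the sexes differ by tissue was tested with the interaction of tissue and sex, in which a positive value means a higher ratio of male to female in the urethra than in the bladder. Nt5e had the smallest p (2.85 ± 0.18, adjusted p = 5.81e-07). It stood at 45.4 ± 8.75 CPM in female and 45.8 ± 7.91 CPM in male bladder (SD, n = 4 each), so that it was the female urethra that stood apart at 7.94 ± 0.54 CPM. Ramp1 (1.79 ± 0.15) stood at 6.15 ± 0.742 CPM in female urethra, 19.9 ± 2.07 in male urethra, 44.3 ± 3.23 in female bladder and 41.5 ± 5.32 in male bladder (SD, n = 4 each). Glp2r (3.78 ± 0.32) stood at 0.524 ± 0.117, 7.2 ± 0.859, 3.39 ± 0.95 and 3.35 ± 0.936 CPM in the same order. The LIM domain gene Lmcd1 (0.99 ± 0.08) and the clusterin gene Clu (1.49 ± 0.14) completed the 5 positive genes with the smallest p. On the negative side Cpxm2 (−2.60 ± 0.32) stood at 2.44 ± 0.316 CPM in male urethra, 14.1 ± 3.62 in female urethra, 31.3 ± 7.92 in male bladder and 29.9 ± 8.12 in female bladder (SD, n = 4 each). Gdf5 (−1.46 ± 0.24) stood at 2.65 ± 0.449, 8.04 ± 1.16, 4.13 ± 0.3 and 4.52 ± 1.12 CPM in the same order. Pamr1 (−0.87 ± 0.11), Lrrtm1 (−1.30 ± 0.21) and the Ikaros family gene Ikzf3 (−1.60 ± 0.26) followed.

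In all 98 genes had a positive and 24 a negative interaction. Leaving out single libraries gave 60 to 119 positive and 9 to 28 negative genes, and the DESeq2 test gave 196 and 78. Without the 3 libraries lowest in epithelium genes the counts were 63 and 8, Ikzf3 was no longer called (adjusted p = 0.0916), and 50.8% of the 122 calls were kept. That fit also has fewer female libraries. With the epithelium score as a covariate the counts were 138 and 39, and 98.4% of the calls were kept. The covariate has the same slope in both tissues, so it cannot settle the part of epithelium in the interaction. With the litter as a block 39 genes were negative in place of 24. The sex comparisons of the 2 tissues come from the same 8 pools of embryos and shared 20 higher genes, where independent lists of these sizes would share 1.8, and 22 lower genes, where they would share 1.5, and 0 genes were called in opposite directions. These comparisons are not independent. Part of the overlap was also fixed in advance, since the 4 tested genes of the Y list were called higher in males in both tissues. The overlap off the sex chromosomes was not counted.

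By list, camera called 11 of 26 for the interaction, 9 positive and 2 negative, and 0 with an estimated correlation. The adjusted p ran from 1.21e-06 for collagen and matrix to 0.0438 for FGF genes. Positive were Hox groups 1 to 8 (median 0.38), endothelium (0.32), mesothelium (0.36), cartilage and bone (0.26), collagen and matrix (0.20), retinoic acid (0.24), immune cell (0.15), pericyte (0.15) and FGF genes (0.09), and negative were neuron (−1.19) and proliferation genes (−0.12). The neuron list was not called without bladder male replicate 3 (median −0.24, adjusted p = 0.221). That library had a mean log2 CPM of neuron genes of 4.76, against 1.83 to 3.49 in the other male bladder libraries. The pericyte and FGF lists each lost the call in 13 of 25 alternatives (adjusted p = 0.0513 to 0.459 and 0.0513 to 0.425). The immune cell list lost it without bladder female replicate 4 (adjusted p = 0.0633), bladder male replicate 4 (0.0575), urethra female replicate 4 (0.0509) or urethra male replicate 2 (0.0631), and the proliferation list without bladder male replicate 1 (0.162). The epithelium list was not called (median 0.01, adjusted p = 0.372), but it was called without bladder female replicate 3 (0.0498), urethra female replicate 1 (0.0155) or urethra female replicate 2 (0.011). Genital duct genes were called without bladder female replicate 1 (0.0112) or 2 (0.0343), bladder male replicate 2 (0.0137) or urethra male replicate 4 (0.0305). Other lists gained a call without a single library: limb, cloacal and genital transcription factors without bladder female replicate 1 (0.0457), smooth muscle genes without bladder female replicate 3 (0.0263) and glia genes without bladder male replicate 4 (0.0214). Among single members, Aldh1a1 (2.23), Ibsp (3.47), Wnt16 (2.36), Sfrp4 (2.55), Bmper (1.2) and Hoxb9 (0.64) were positive.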

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

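The tests of the epithelium and muscle patterns below, the interaction median of the epithelium list and the residual correlation were chosen after the results were seen.

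Single libraries lay apart from the rest of their group in 6 of 66 groups tested, where chance alone gives about 1 in 20. The total of urethra female replicate 2 was 24447435 counts (others 29244266 to 29698009). Bladder female replicate 3 had 5.11 CPM of Sall1 (other bladder libraries 0.224 to 2.33). Bladder male replicate 3 had 281 CPM of Ckm (192 to 234) and urethra male replicate 3 had 7.41 (1.04 to 3.91). Bladder male replicate 1 had 2.51 CPM of Crabp1 (6.67 to 6.94), and bladder female replicate 4 had 30.4 CPM of Tbx18 (22 to 23.2).

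Of 163 named genes 20 differed between the tissues in the ratio of male to female, by the interaction test. The higher ratio was in the urethra for Nt5e (2.85), Ramp1 (1.79), Glp2r (3.78), Lmcd1 (0.99), Clu (1.49), Aldh1a1 (2.23), Stat5a (1.21), Bmper (1.2), Ibsp (3.47), Sfrp4 (2.55), Wnt16 (2.36), Adam12 (0.76) and Hoxb9 (0.64). It was in the bladder for Pamr1 (−0.87), Cpxm2 (−2.60), Ikzf3 (−1.60), Gdf5 (−1.46), Lrrtm1 (−1.30), Pnoc (−3.58) and Dsc3 (−1.68). By list the medians were 0.38 for Hox groups 1 to 8, −1.19 for neuron, 0.32 for endothelium, 0.15 for pericyte and 0.15 for immune cell genes. They were 0.36 for mesothelium, 0.26 for cartilage and bone, 0.20 for collagen and matrix, 0.09 for FGF, 0.24 for retinoic acid and −0.12 for proliferation genes. With an estimated correlation 0 of these 11 lists were called. The neuron median was −0.24, and the list was not called (adjusted p = 0.221), without bladder male replicate 3. That library had the highest mean log2 CPM of neuron genes in male bladder (4.76, others 1.83 to 3.49). This mean was not among the 6 values that lay apart from their group.

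More genes differed between the sexes in the urethra (1167) than in the bladder (106). Deeper urethra libraries are excluded as the cause, since with each library thinned to the smallest total the counts were 1008 and 135. Unequal carry-over of epithelium stays open as a cause. With the epithelium score as a covariate the counts were 491 and 30, and 37.2% of the urethra calls were kept. That fit gives each gene the same slope in both tissues, so it cannot exclude carry-over whose effect differs between them. The interaction median of the epithelium list was 0.01, but it ran from −0.15 to 0.32 without single libraries, so whether its sex difference differed by tissue stays open. The counts also depend on how far libraries of a group spread, and whether that spread differed between the tissues was not tested. With only the libraries compared in the fit, 8 genes were higher and 8 lower in male bladder, and 737 and 475 in male urethra. In the simulated data 45.3% of 1.5-fold changes were recovered in the bladder and 65.6% in the urethra. For 2-fold changes these were 83.6% and 83.3%. A difference of the tissues in their response to sex stays open as a hypothesis, and it was not tested apart from the libraries that show it.

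Epithelium genes were higher in males in both tissues (list medians 0.59 in the bladder and 0.63 in the urethra), with adjusted p = 0.404 and 0.602 with an estimated correlation and 0.165 and 0.0641 with fry. In the bladder 0 and in the urethra 4 of 24 members were called. The genes rose and fell together between libraries of a group (residual correlation 0.79), which is consistent with epithelium carried over in unequal amounts. All 24 list genes were tested in these mesenchyme libraries. Without the 3 libraries lowest in these genes the median was 0.46 in the bladder and 0.19 in the urethra. These libraries were picked by the same genes, only 1 of them is from the bladder, and the bound was set apart by tissue after the result was seen, so this leaves open how much a few low female libraries account for. A sex difference in epithelium or in the ease of its removal stays open as well.

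Ckm, Acta1 and 4 more skeletal muscle list genes were higher in the bladder. Carried-over skeletal muscle like that of the urethra is excluded, since it would have to be more abundant in the bladder, while 20 of 26 list members were higher in the urethra and Mylpf and Myh3 stood at only 1.95 and 5.13 CPM in the bladder, against 1210 for Acta1. Muscle of another maturity stays open. Of the 10 members most abundant in the urethra 7 were higher there, a test that was tried and decides nothing, since it picks members by that level. Reads of Acta2 counted for Acta1 are excluded as the whole cause, since their log2 fold changes differed by 2.64 (combined standard error 0.26). Expression of these genes by bladder smooth muscle may explain the pattern, as a hypothesis that was not tested.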

How the results depend on the processing

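The fits with the epithelium covariate, with 3 libraries left out, with thinned counts and with library totals alone were chosen after the data were seen. Between the tissues no count of genes moved by over 1.5 times in any alternative. For male against female in the bladder (45 higher, 61 lower) the counts higher were 90 without filter, 231 with the DESeq2 test, 8 with only the libraries compared, 29 without genes of X, Y and M, 10 with the epithelium covariate and 18 with 3 libraries lowest in epithelium genes left out. The counts lower were 249 with the DESeq2 test, 8 with only the libraries compared and 20 with the covariate. In the urethra (725 higher, 442 lower) they were 353 and 138 with the covariate, 314 and 128 with the 3 libraries left out, and 697 lower with the DESeq2 test. The interaction (98 and 24) had 196 and 78 with the DESeq2 test, 63 and 8 with the 3 libraries left out, and 39 lower with each replicate block and with the covariate. The replicate block changed, among the lists, the calls of genital duct (adjusted p = 0.107) and cartilage and bone (0.0739) between tissues and of steroid hormone genes for the interaction (0.0434), and among named genes Mid1 in the bladder (0.0356) and Utp14a in the urethra (0.0382); it changed no other call of a named gene or list.

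Of the lists called (17 for tissue, 12 and 10 for the sexes in bladder and urethra), an estimated correlation left 2, 2 and 2. For the interaction (11 lists) the estimated correlation and fry each left 0. Fry left 3 in the bladder and 6 in the urethra. Between the tissues fry called 22 of 26 lists. Among these were 5 lists that camera at the fixed correlation did not call. They were hedgehog (fry, adjusted p = 4.32e-04), immediate early (4.04e-05), red blood cell (0.00473), X inactivation (7.55e-07) and epithelium genes (0.0489). With the covariate 7 were called in the bladder, 6 of the 12 and the Hox groups 1 to 8 anew. The collagen list turned higher in male urethra with the epithelium covariate (adjusted p = 0.0495). The epithelium list turned to the negative side for the interaction with the 3 libraries lowest in epithelium genes left out (0.004). The p of neuron genes, male versus female, bladder, ranged from adjusted p = 1.79e-08 without bladder male replicate 1 to 0.513, in the other direction, without bladder male replicate 3.

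Without single libraries, male bladder had 10 (without bladder female replicate 4) to 82 (without bladder female replicate 1) genes higher and 30 (bladder female replicate 4) to 103 (bladder female replicate 2) lower. Male urethra had 447 (urethra male replicate 4) to 897 (urethra female replicate 1) higher and 227 (urethra male replicate 4) to 794 (urethra female replicate 1) lower. The interaction had 60 (urethra male replicate 2) to 119 (bladder female replicate 2) positive and 9 (bladder male replicate 3) to 28 (bladder female replicate 2) negative. Counts also moved by over 1.5 times in the bladder without bladder female replicate 3 (12 higher), bladder male replicates 2 (27), 3 (17) and 4 (29 higher, 37 lower) and 1 (40 lower), bladder female replicate 1 (92 lower) and urethra female replicate 3 (29), urethra male replicates 1 (29) and 3 (23). They did so in the urethra without urethra female replicates 3 (479 higher, 266 lower) and 4 (474, 244) and urethra male replicates 1 (269 lower) and 2 (261 lower), and for the interaction without urethra male replicates 1 (65 positive, 12 negative), 2 (10 negative) and 4 (12), urethra female replicates 3 (15) and 4 (13) and bladder female replicates 1 (14) and 4 (10). Of 202 results for named genes, 1907 of 2020 values in other settings kept direction and side of the threshold, and 0 reversed.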

Other observations

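The gene families in the first paragraphs were chosen after their values were seen, while the counts over other groupings of the libraries were planned. Of 81 genes of oxidative phosphorylation 80 were lower in the urethra than in the bladder (median −0.92, and −0.78 with library totals alone), among them Ndufa4 (−1.53 ± 0.06) and Cox6c (−0.85 ± 0.05). Other genes matched in length and expression had a median of −0.38. Of 81 cytosolic ribosomal protein genes 80 fell (median −0.61, and −0.47 with library totals alone), as with Rpl3 (−0.45 ± 0.06), and matched genes had −0.37. Neuron and glia genes were higher in the urethra (list medians 3.88 and 2.11), and the next families were not tested apart from them. All 6 Slit and Robo genes rose (median 1.29), with Robo1 at 1.74 ± 0.12, as did 8 of 8 ephrin genes (median 0.69), with Efnb1 at 0.82 ± 0.06, and of 14 Eph receptor genes 10 rose and 3 fell, with Epha5 at 3.42 ± 0.16. Of 65 protocadherin genes 61 rose and 2 fell (median 1.21, matched genes 0.22), although cluster members share exons and their counts are less certain.

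Between the sexes, Klf15 (1.83 ± 0.14), Fkbp5 (1.15 ± 0.11), Cyp1b1 (2.31 ± 0.18) and the lipocalin gene Apod (2.09 ± 0.25) were higher in male urethra, each with a called interaction (1.57, 1.06, 2.36 and 2.40). The early B-cell factor gene Ebf2 was lower in male bladder (−2.55 ± 0.38), and its interaction was 2.78 ± 0.49. The serotonin receptor gene Htr1a was lower in male urethra (−3.21 ± 0.38), and the matrix metalloprotease gene Mmp7 higher (4.89 ± 0.36).

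The libraries were also regrouped to count how often another grouping called as many genes. For the tissues 1 of 100 groupings drawn from 2450, the real one, gave 13683 genes. The next 3, with 11392, 11191 and 8640 genes, parted 6 of 8 pairs, and of the other draws that parted 8 pairs the highest had 42. Among 100 drawn from the 128 groupings within pairs the real one was again the 1 with as many, and the highest other had 10908. For females 1 of 35 gave 12001 (highest other 3618) and for males 1 of 35 gave 11679 (2). For the sexes 1 of 35 gave 106 in the bladder (14) and 1 of 35 gave 1167 in the urethra (1), and for the interaction 1 of 35 gave 122 (1). For the tissues of both sexes chance is thus excluded for the count of genes within pairs. Over groupings of any kind the shares were low too, but most of these groupings break the litter pairs. The sex counts also hold X and Y genes, which only the real grouping parts by sex. These shares therefore do not exclude chance for the other 5 comparisons. In each of those only 8 groupings part 4 of 4 pairs, too few for a share under 0.05. The 7 others gave at most 1 gene. Chance is not excluded for the counts of gene lists, where 12 of 100 groupings gave at least 17 lists between tissues (highest other 19), 13 of 35 gave at least 12 in the bladder (16), 8 of 35 at least 10 in the urethra (12) and 9 of 35 at least 11 for the interaction (13).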
